A study of Mus musculus with 6 samples.

How the data were processed

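Tongue tumours were raised by injecting 4MOSC1 control cells or 4MOSC1 cells overexpressing LIGHT into the tongue of C57BL/6 mice, per the labels' protocols. RNA was extracted from tumour tissue and ribosomal RNA was depleted by an RNase H or Ribo-Zero method, per the labels' protocols. The submitters' processing notes name HISAT, Bowtie2 and the genome build GRCm38.p6, with no role or version; the quantifier, annotation and filters are not given in the sources used here. The deposited values are TPM per gene, rounded to 2 decimals, and per the file headers there is 1 TPM column per library. Each column sums to the same total over the 18437 genes listed, so depth is unknown and no counting interval can be given. Of the gene symbols, 18361 matched a GRCm38.p6 gene table, and 18256 of these (99.4%) are protein coding. A specimen holds tumour cells, infiltrating cells and tongue tissue, so a change in TPM can come from a change in cell composition as well as in expression. Because TPM are shares of 1 total, a rise of some abundant genes lowers the values of the others.

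The labels give the group and replicate number of each of the 6 libraries. They describe injection of each mouse but tie no library to an animal, so the p-values measure the spread between these samples. No 2 libraries held identical values. The numbers were not treated as pairing the samples.

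Genes at 1 TPM or more in at least 3 libraries (13167) were tested on log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend), 2-sided, with Benjamini-Hochberg adjusted p under 0.05 and no minimum fold. A gene under 1 TPM throughout 1 group was tested only if all 3 libraries of the other group reached 1 TPM. For such a gene the filter sets the direction of the change. Gene lists were tested with camera from limma at a preset inter-gene correlation of 0.01, adjusted over the lists with 5 or more tested members, with an estimated correlation and with fry beside it. Tnfsf14 also had an exact permutation test. The tests, alternatives, 32 gene lists and the rule for named genes were chosen before the data were examined. The named genes are Tnfsf14, Tnfrsf14, Ltbr, Lta and Ltb; the 10 largest rises and 10 largest falls among genes with an adjusted p under 0.05 whose 3 LIGHT libraries lie all above or all below the control libraries and whose higher group mean is at least 1 TPM, leaving out receptor and immunoglobulin segments and provisional gene models; and up to 4 members of each list by smallest unadjusted p. Another 14 lists were chosen after seeing the data and are used only in the closing observations.

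Alternatives were pseudocounts of 0.1 and 0.5, no filter on low values, a filter at 5 TPM, trimmed-mean (TMM) factors computed on the TPM with 30% of log ratios and 5% of levels trimmed on each side, quantile normalization, each library left out in turn, the replicate number as a block, the mean of the skeletal muscle or basal keratinocyte list as a covariate, limma without the trend, robust limma, a minimum absolute log2 fold change of 1 and removal of the skeletal muscle genes. A haemoglobin covariate was added after seeing the data. The tests were tried on simulated data for the LIGHT against control comparison, with the real gene means and spreads and 200 genes changed. Of genes changed by 1 on the log2 scale 72.5% were called (13123 genes tested), and of those changed by 2 94.9% (13100 genes tested). Of genes changed by 0.5 on the log2 scale 0% were called (13122 genes tested). False calls were 2.03% and 6.93% of all calls at the 2 larger sizes. The simulation changed far fewer genes than the 3037 called in the data, which makes the adjusted threshold stricter. Called lower genes in the data had a median log2 fold change of -0.53. The simulated shares, with the 0% among them, therefore do not describe the real comparison. Results for 2 genes are not reported here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.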

Results

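The data are bulk RNA-seq measurements of tongue tumours grown in C57BL/6 mice from 4MOSC1, a mouse oral squamous cell carcinoma line. One group received control cells and the other received 4MOSC1 cells overexpressing LIGHT, the TNF superfamily ligand encoded by Tnfsf14, whose receptors are the herpesvirus entry mediator (Tnfrsf14) and the lymphotoxin beta receptor (Ltbr). There were 3 control and 3 LIGHT tumour libraries. Total RNA had been depleted of ribosomal RNA, and the values are TPM, a length-corrected share of transcripts, for 18437 genes. TPM keeps no sequencing depth, so the depth behind each value is unknown. Between 12713 and 12838 genes reached 1 TPM in the control libraries and between 13183 and 13271 in the LIGHT libraries. The comparison asks which genes and gene groups differed between LIGHT and control tumours, in a study whose title concerns tertiary lymphoid structures, the organised lymphocyte aggregates that can form in inflamed tissue. Fold changes are differences of log2(TPM + 1), which understate the change of low genes.

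Tnfsf14 was listed at 0.66 ± 0.13 TPM in the control tumours and 25.3 ± 1.28 TPM in the LIGHT tumours (mean ± SD, n = 3 each). The mean was 38.4-fold higher in LIGHT tumours, with a log2 fold change of 3.99 (SE 0.11, limma adjusted p = 7.01e-06). The gene lies on chromosome 17 from 57189474 to 57194181 (GRCm38.p6). An exact two-sided permutation test of the 6 values gave p = 0.1, the smallest that 20 assignments allow. Tnfrsf14 rose from 7.97 ± 0.83 to 16.9 ± 2.17 TPM (log2 fold change 1.00, SE 0.12, limma adjusted p = 0.00253). Ltb, the membrane partner of lymphotoxin alpha, rose from 9.27 to 25.7 TPM (log2 fold change 1.47, limma adjusted p = 0.0106), and Lta rose from 1.21 to 3.21 TPM (log2 fold change 0.92, limma adjusted p = 0.0195). The call of Lta was lost in 6 of 17 other settings, among them without control replicate 1, control replicate 2 or LIGHT replicate 2. Ltbr was at 88.3 TPM in control and 71.5 TPM in LIGHT tumours and missed the threshold (limma adjusted p = 0.0535), but passed it as lower in 6 of 18 other settings (adjusted p = 0.0064 with trimmed-mean scaling).

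Among the 13167 genes tested, 2325 were higher and 712 lower in LIGHT tumours. The largest rises after Tnfsf14 included the granzymes Gzmg (3.34 to 49.2 TPM, log2 fold change 3.60) and Gzmd (6.28 to 57.9 TPM, 3.03), proteases of cytotoxic lymphocyte granules. Spib, an ETS transcription factor of B cells, plasmacytoid dendritic cells and intestinal microfold cells, went from 0.69 ± 0.09 to 14.1 ± 2.38 TPM (log2 fold change 3.16, SE 0.14, limma adjusted p = 7.03e-05). Alox12e, an epidermal lipoxygenase, went from 11.3 to 114 TPM, Mill1, an MHC class I-like gene, from 1.87 to 21.7 TPM, and Wfdc18 from 28.7 to 184 TPM. Ccdc33, Fcgbp and Ear2 also rose, with log2 fold changes of 3.10, 2.87 and 2.86. The largest falls were in Sprr2k (127 to 22.6 TPM, log2 fold change -2.54), a small proline-rich gene of the cornified envelope, and Oit1 (30.8 to 5.07 TPM, -2.39). Klk6, a kallikrein protease, Aldh1a7, Defb14, a beta-defensin, and Il24, a cytokine of the interleukin-10 family, fell by 2.31, 2.29, 2.24 and 2.22 on the log2 scale. Emp1 dropped from 1517 ± 103 to 361 ± 61.2 TPM (log2 fold change -2.08). Ppbp, a chemokine, Lilra6 and Spink12 fell by 1.98, 2.04 and 1.97.

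The higher calls were 76.6% of all calls with the TPM as deposited, 44.9% after trimmed-mean factors and 43.6% after quantile normalization. The median log2 fold change of all tested genes was 0.09, -0.04 and -0.04 under these scalings, so the excess of higher calls depends on the scaling. No gene called with the deposited values changed sign under either. In 41.2% of tested genes the 3 LIGHT libraries lay all above or all below the 3 control libraries, against 10% by chance. The counts moved by over 1.5 times when a library was left out: 1289 genes were higher without control replicate 3 and 1264 without LIGHT replicate 3, and the lower genes numbered 422, 394, 433, 371 and 325 without control replicates 1, 2 and 3 and LIGHT replicates 2 and 3.

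**Figure D1:**
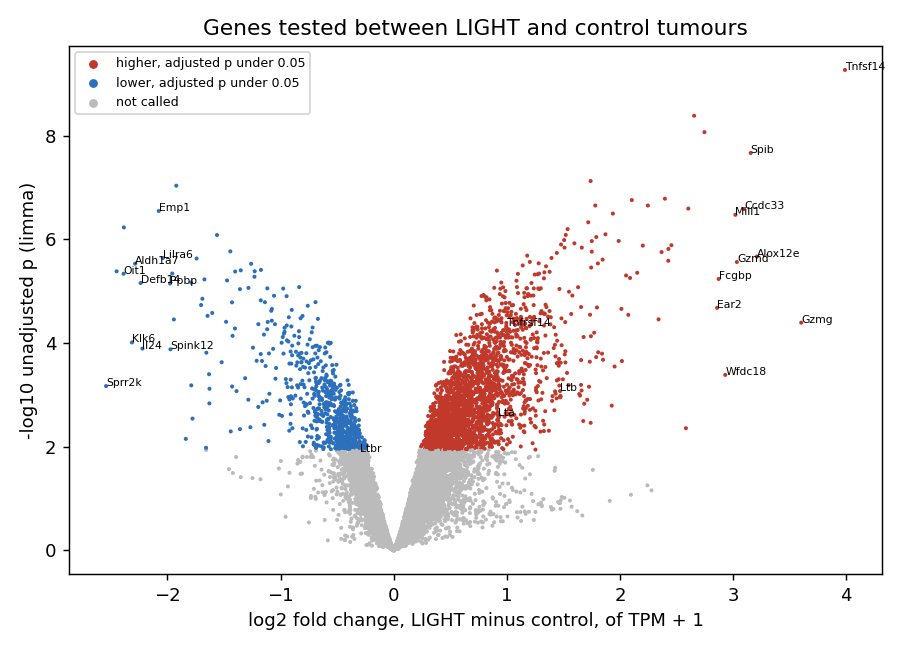
Each point is 1 of the 13167 tested genes, with the log2 fold change of TPM + 1 (LIGHT minus control) on the x axis and -log10 of the unadjusted limma p on the y axis; red and blue mark adjusted p under 0.05. There are 2325 red and 712 blue points, a ratio that depends on the scaling (76.6% of calls higher as deposited, 44.9% after trimmed-mean factors), and Tnfsf14 lies farthest right at 3.99.

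**Figure D2:**
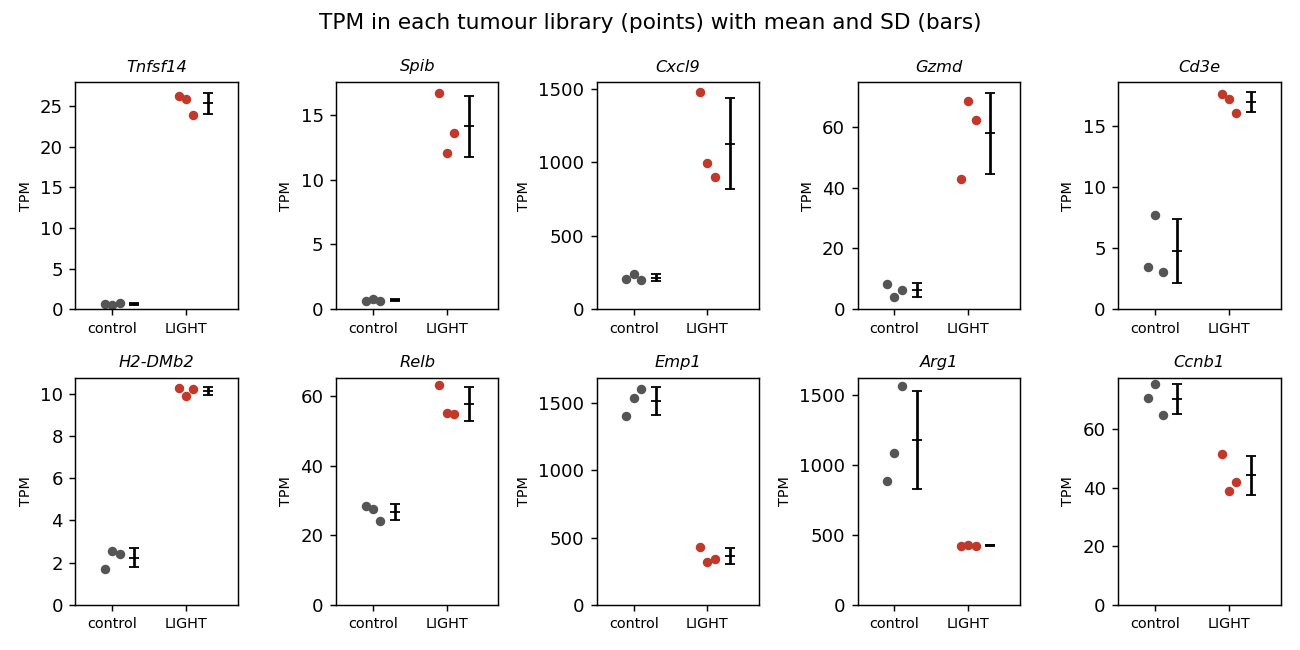
TPM (y axis, linear from 0) of 10 named genes in the 3 control (grey) and 3 LIGHT (red) tumour libraries; bars give the mean and SD. All 3 LIGHT points lie above all control points for Tnfsf14, Spib, Cxcl9, Gzmd, Cd3e, H2-DMb2 and Relb and below them for Emp1, Arg1 and Ccnb1. The rule for the largest rises and falls, here Tnfsf14, Spib, Gzmd and Emp1, requires this separation, so for them it is no separate result.

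Of 32 gene lists fixed before the data were examined, 29 had at least 5 tested members. The competitive set test camera with a preset correlation of 0.01 called 18 lists higher and 4 lower. With an estimated correlation it called 0 lists in either direction (adjusted p from 0.278 to 0.614 for the called lists), while 4 lists had an unadjusted p under 0.05, and the self-contained test fry called 14 higher and 1 lower. Camera with the preset correlation also called 8 to 20 lists when the 6 libraries were split in the other 9 ways, so its list calls alone do not single out the LIGHT grouping. The number of single genes called was 0 in each of those splits, against 3037 in the real grouping, at an adjusted p under 0.05, with 85 to 841 genes at an unadjusted p under 0.05. Each of those splits put control and LIGHT libraries in unequal numbers on both sides. Part of the group difference thus stayed in the contrast, and the rest widened the spread within each side. Neither count therefore shows what libraries without a group difference would give.

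In the noncanonical NF-kB and lymphotoxin list 12 of 16 members rose (13 rose and 1 fell adjusted over the list alone), among them Relb (26.7 to 57.7 TPM), Nfkb2 (47.3 to 94 TPM) and Birc3 (10.7 to 19.5 TPM), the first 2 encoding subunits of the noncanonical pathway (camera adjusted p = 6.8e-05, and adjusted p = 0.35 with an estimated correlation). With the skeletal muscle covariate 7 of the 16 passed, at a median log2 fold change of 0.89 (median SE 0.19) against 0.79 (0.12). Of 9 tested lymphoid chemokines 4 rose, and 4 adjusted over the list alone: the T cell attractants Cxcl9 (213 to 1128 TPM) and Cxcl10 (374 to 1505 TPM), and Ccl21a (41.8 to 92.9 TPM) and Ccl19 (1.24 to 4.28 TPM), ligands of the homing receptor Ccr7 (camera adjusted p = 0.0338, and adjusted p = 0.379 with an estimated correlation). The list call was lost without control replicate 1 (adjusted p = 0.0699) or LIGHT replicate 2 (0.0668), with the filter at 5 TPM (0.0601) and with the basal keratinocyte covariate (0.0688). With the skeletal muscle covariate 2 members passed, at a median log2 fold change of 0.43 (median SE 0.32) against 0.48 (0.24). The near-identical copies of Ccl21a can share reads with it. In the high endothelial venule and lymphoid stroma list 8 of 12 rose, and 8 adjusted over the list alone, including the adhesion molecules Vcam1 (6.91 to 24.3 TPM) and Icam1 (73.1 to 169 TPM), and Il7 and Chst2 (camera adjusted p = 0.00114, and adjusted p = 0.353 with an estimated correlation). That count was 5 without control replicate 3 or LIGHT replicate 3, after quantile normalization and with the haemoglobin covariate, and 2 with the skeletal muscle covariate, at a median log2 fold change of 0.79 (median SE 0.27) against 0.66 (0.18). Of the 16 members fixed beforehand, Glycam1, Chst4, Madcam1 and Clec1b did not pass the filter on low values. Their means went from 0 to 0.21, 0.06 to 0.18, 0 to 0.06 and 0.43 to 1.59 TPM.

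Of 18 B cell markers fixed beforehand, 16 were matched and 3 of these passed the filter on low values, Spib, Cd22 and Cd72. All 3 rose, as they did adjusted over the list alone. Spib and Cd22 were under 1 TPM in every control library. They passed the filter only through the LIGHT libraries, so the filter set the direction of their change. Too few were tested for a set test. Without LIGHT replicate 2, after quantile normalization or with the haemoglobin covariate 1 of the 3 was called. Ms4a1, Cd79a and Pax5, chosen for mention after their values were seen, did not exceed 0.68 TPM in any library, while Cd79b, also chosen so, went from 0.18 ± 0.03 to 1.18 ± 0.22 TPM. In the plasma cell list 4 members were tested. Irf4 rose and Prdm1 fell, and 1 rose and 1 fell adjusted over the list alone. Irf4 too was under 1 TPM in every control library and passed the filter only through the LIGHT libraries. The call of Irf4 was lost with the skeletal muscle or the haemoglobin covariate. Of 14 T follicular helper and germinal centre genes fixed beforehand, 6 passed the filter on low values. The median over all 14 was 0.35 TPM in control and 0.64 TPM in LIGHT tumours. Of the 6 tested genes 5 rose (6 adjusted over the list alone), including Icos (4.37 to 11 TPM), Pdcd1 (3.73 to 11.4 TPM) and S1pr2 (camera adjusted p = 0.00121, and adjusted p = 0.278 with an estimated correlation). 3 passed with the skeletal muscle or the haemoglobin covariate, at a median log2 fold change of 0.75 and 0.84 (median SE 0.20 and 0.19) against 0.85 (0.15). Pdcd1 was also a member of the immune checkpoint list.

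Of 17 T cell markers 15 rose (17 adjusted over the list alone), with a median log2 fold change of 1.28. The T cell count was 10 without control replicate 3 and 12 without control replicate 1 or LIGHT replicate 2 or 3. Cd3e, a chain of the T cell receptor complex, went from 4.75 ± 2.60 to 17 ± 0.8 TPM and Cd2 from 12.7 to 32.5 TPM (camera adjusted p = 1.28e-06, and adjusted p = 0.379 with an estimated correlation). Of 19 cytotoxic effector genes 15 rose (17 adjusted over the list alone), with a median of 1.65. The cytotoxic count was 11 without control replicate 3. Gzmc went from 28.3 to 120 TPM, Gzme from 2.57 to 18.5 TPM and Cst7 from 8.58 to 22.8 TPM (camera adjusted p = 4.04e-07, and adjusted p = 0.278 with an estimated correlation). Granzyme genes are close paralogs and can share reads. Among natural killer cell markers 4 of 5 rose (5 adjusted over the list alone), with Ncr1 at 0.46 and 2.08 TPM (camera adjusted p = 0.00735, and adjusted p = 0.353 with an estimated correlation). The natural killer count was 2 without control replicate 3. Among these rises, Gzma was also a member of the cytotoxic list, so it is not a separate result. Ncr1 and Sh2d1b1 were under 1 TPM in every control library and passed the filter only through the LIGHT libraries. Haemoglobin transcripts also varied, with Hba-a1 at 28.7, 153 and 37.3 TPM in the control and 38.2, 773 and 307 TPM in the LIGHT libraries, and with their mean as a covariate, chosen after seeing the data, 3 T cell, 8 cytotoxic and 1 natural killer gene passed. Their median log2 fold changes were then 1.10, 1.35 and 1.05, against 1.28, 1.65 and 1.08. The median SE was 0.26, 0.35 and 0.24, against 0.22, 0.27 and 0.19. The lost calls thus went with a wider SE and, for T cell and cytotoxic genes, a smaller change. Among all tested genes 946 were higher and 203 lower with this covariate, against 2325 and 712, which makes the adjusted threshold stricter. These parts were not told apart.

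Of 9 regulatory T cell markers 7 rose (7 adjusted over the list alone), including Lrrc32 (3.58 to 9.85 TPM), Ccr8 (2.18 to 5.89 TPM) and Tnfrsf4 (camera adjusted p = 0.000361, and adjusted p = 0.278 with an estimated correlation). Of 14 checkpoint genes 11 rose (12 adjusted over the list alone), including Lag3 (6.1 to 19.7 TPM) and Ctla4 (4.31 to 11.4 TPM), receptors that restrain T cells (camera adjusted p = 1.05e-05, and adjusted p = 0.35 with an estimated correlation). Ctla4 was also in the regulatory T cell list, and Btla and Cd160 were also in the noncanonical NF-kB and lymphotoxin list. The rises of these genes are therefore not separate results.

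All 10 tested MHC class II genes rose, also adjusted over the list alone, among them Cd74 (1210 to 3195 TPM), H2-Eb1 (201 to 469 TPM) and H2-DMb2 (2.23 to 10.1 TPM), and all 10 did so without any 1 library (camera adjusted p = 4.04e-07, and adjusted p = 0.35 with an estimated correlation). In the MHC class I list 7 of 15 rose (8 adjusted over the list alone), such as Tap2 (88.8 to 161 TPM) and Tapbp (camera adjusted p = 0.0198, and adjusted p = 0.602 with an estimated correlation). The count was 2 without control replicate 3 or LIGHT replicate 1, 3 without control replicate 1 or LIGHT replicate 2, 3 after trimmed-mean scaling, and 2 after quantile normalization or with either of the muscle and haemoglobin covariates. With these 2 covariates the median log2 fold change was 0.49 and 0.46 (median SE 0.18 and 0.15), against 0.41 (0.12) without. The class I list call was lost without LIGHT replicate 1 (adjusted p = 0.0571) and with fry (0.0864). Of 23 interferon response genes 14 rose (20 adjusted over the list alone), including Gbp5 (31 to 103 TPM) and Ifit3 (48 to 176 TPM), with camera adjusted p = 5.23e-06, and adjusted p = 0.507 with an estimated correlation. 9 rose without control replicate 3. With the haemoglobin covariate 7 rose, at a median log2 fold change of 0.87 (median SE 0.23) against 0.75 (0.19). The call was lost with fry, by a margin beyond the digits printed here.

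Of 8 dendritic cell genes 6 rose, and 6 adjusted over the list alone, including Ccl22 (1.89 to 12.8 TPM) and Ccr7 (1.54 to 4.12 TPM), with camera adjusted p = 0.00114, and adjusted p = 0.278 with an estimated correlation. Of 18 macrophage and monocyte genes 10 rose and 1 fell (13 and 1 adjusted over the list alone): Nos2, the inducible nitric oxide synthase, went from 12.2 ± 1.22 to 31.0 ± 4.27 TPM, Apoe from 271 to 597 TPM and C1qc from 136 to 257 TPM. Arg1, arginase 1, dropped from 1180 to 427 TPM (camera adjusted p = 0.00121, and adjusted p = 0.397 with an estimated correlation). 5 rose with the skeletal muscle covariate, at a median log2 fold change of 0.65 (median SE 0.22) against 0.70 (0.15). Of 13 neutrophil genes 1 fell, Stfa2 (23.8 to 5.47 TPM), and 1 adjusted over the list alone. Camera called the list lower (median log2 fold change -0.17, adjusted p = 0.0338, and adjusted p = 0.518 with an estimated correlation). The neutrophil call was lost after trimmed-mean scaling (adjusted p = 0.216), quantile normalization (adjusted p = 0.176), without control replicate 3, LIGHT replicate 1 or LIGHT replicate 2, with the filter at 5 TPM, with the skeletal muscle covariate and with fry (adjusted p from 0.101 to 0.511). In the mast cell and eosinophil list 1 of 6 rose, Kit, and the list was not called (adjusted p = 0.979).

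Of 20 proliferation genes 16 fell and 0 rose (19 fell adjusted over the list alone), with a median log2 fold change of -0.39 that was -0.52 after trimmed-mean scaling. Ccnb1, cyclin B1, dropped from 70.2 ± 5.23 to 44.2 ± 6.60 TPM, Mcm2 from 41.1 to 26.5 TPM and Bub1 from 20.4 to 12.3 TPM (camera adjusted p = 8.61e-12, and adjusted p = 0.353 with an estimated correlation). The number of falls was 5, 4, 5 and 3 without control replicates 1 and 2 and LIGHT replicates 2 and 3. It was 0 with the skeletal muscle or the haemoglobin covariate, where the median log2 fold change was -0.42 and -0.35 and the median SE 0.18 and 0.13, against 0.11 without a covariate. All 20 genes kept their direction. With the muscle covariate the median change was no smaller, while the SE was wider. The adjusted threshold was also stricter, since 652 genes were higher and 98 lower with it, against 2325 and 712.

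Of 21 differentiated squamous genes 5 fell and 2 rose (5 and 3 adjusted over the list alone): Sprr1a dropped from 12302 to 4341 TPM, Sprr1b from 2049 to 659 TPM and Cnfn from 5164 to 2893 TPM, all cornified envelope genes, and Krtdap from 12379 to 8636 TPM (camera adjusted p = 0.0134, and adjusted p = 0.602 with an estimated correlation). The falls numbered 3 without control replicate 2 or 3, and the rises 0 without control replicate 1 or 2 or LIGHT replicate 2 or 3. With the skeletal muscle covariate 1 fell and 0 rose, and with the haemoglobin covariate 3 fell and 0 rose. After trimmed-mean scaling 5 fell and 0 rose, and after quantile normalization 4 fell and 1 rose. With the replicate block 7 fell and 5 rose. Of 19 basal keratinocyte and tumour cell genes 1 fell, Krt6a (8625 to 5695 TPM), and 0 passed adjusted over the list alone. After trimmed-mean scaling 4 fell, after quantile normalization 0 fell, and with the replicate block 4 fell and 1 rose. Krt14 was at 11421 and 8916.5 TPM (camera adjusted p = 0.0262, and adjusted p = 0.614 with an estimated correlation). Both list calls were lost after trimmed-mean scaling (adjusted p = 0.186 for the differentiated squamous epithelium list and 0.084 for the basal keratinocyte and tumour cell markers list), after quantile normalization (0.432 and 0.641) and with fry (0.430 and 0.665). The first was also lost without control replicate 3 or LIGHT replicate 1 (adjusted p = 0.163 and 0.427), and the second without control replicate 1 or LIGHT replicate 2 (adjusted p = 0.178 and 0.117), with the filter at 5 TPM (0.0536) and with the basal keratinocyte or haemoglobin covariate (0.092 and 0.477). The basal keratinocyte covariate is the mean of that same list, so the loss with it is by construction. In the epithelial-mesenchymal list 6 of 17 rose (7 adjusted over the list alone), including Vim and Tgfbi, and the list was not called (adjusted p = 0.075). It was called higher after trimmed-mean scaling (adjusted p = 0.0268) and quantile normalization (0.0404) and without control replicate 1 (0.0143) or LIGHT replicate 1 (0.0483). In it 3 rose without LIGHT replicate 3 or with the haemoglobin covariate, and 0 with the skeletal muscle covariate. Neither the hypoxia and glycolysis list, with Egln3 and Vegfa higher and Ldha lower (adjusted p = 0.707), nor the oxidative phosphorylation list, with Ndufa4 lower (adjusted p = 0.411), was called. 2 higher and 1 lower, and 1 lower, passed adjusted over each list alone. The oxidative phosphorylation list was called lower without LIGHT replicate 2 (adjusted p = 0.0286) and with the skeletal muscle or haemoglobin covariate (0.00367 and 0.0211).

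In the stromal and host tissue lists, 2 of 16 fibroblast and matrix genes rose, Thy1 and Tagln, and the list was not called (adjusted p = 0.206), except as higher without control replicate 1 (adjusted p = 0.0313) or LIGHT replicate 1 (0.0242). Camera called endothelial genes higher, with 2 of 14 up (Vwf and Cldn5; adjusted p = 0.0266, and adjusted p = 0.614 with an estimated correlation). It also called lymphatic endothelial genes, with 3 of 5 up (Ccl21a, Pdpn and Flt4; adjusted p = 0.0266, and adjusted p = 0.366 with an estimated correlation), and adipocyte genes, with 2 of 5 up (Cidea and Pnpla2; adjusted p = 0.0266, and adjusted p = 0.504 with an estimated correlation). Adjusted over the list alone, 2, 2, 3 and 3 members of these 4 lists rose. Among the lymphatic endothelial rises, Ccl21a was also a member of the lymphoid chemokine list. Pdpn was also in the high endothelial venule and lymphoid stroma list, so these 2 rises are not separate results. The endothelial call was lost without control replicate 3 or LIGHT replicate 3 (adjusted p = 0.102 and 0.129), with the filter at 5 TPM (0.0743) and with fry (0.164), and the lymphatic endothelial call without LIGHT replicate 2 (0.0668). With the skeletal muscle covariate the endothelial, lymphatic endothelial and adipocyte calls were lost (adjusted p = 0.105, 0.185 and 0.185), as with the haemoglobin covariate (0.0708, 0.0708 and 0.061). Their median log2 fold changes were 0.49, 0.53 and 0.39 with the muscle covariate and 0.56, 0.65 and 0.69 with the haemoglobin covariate. Without a covariate they were 0.59, 0.63 and 0.74. Skeletal muscle genes were called higher, with 1 of 23 up (Ryr1) and 0 adjusted over the list alone (median log2 fold change 0.54, adjusted p = 0.00931, and adjusted p = 0.602 with an estimated correlation). The call was lost without control replicate 2 (adjusted p = 0.0856), with the haemoglobin covariate (0.0533) and with fry (0.152). The muscle count was 13 without control replicate 1 and 5 without LIGHT replicate 1. Ckm, creatine kinase, was at 149 ± 60.0 and 355 ± 185 TPM. Nerve and Schwann cell genes (adjusted p = 0.283) and red blood cell genes (1 of 5 up, Bpgm, and 1 adjusted over the list alone; median log2 fold change 2.10, adjusted p = 0.139) were not called. The red blood cell list was called higher without LIGHT replicate 1 (5 of 5 up, adjusted p = 0.00907), without control replicate 2 (adjusted p = 0.0422) and after quantile normalization (adjusted p = 0.048). Of 2 tested salivary gland genes Amy1 rose and Bpifb1 fell, also adjusted over the list alone. Apart from the lymphatic endothelial genes, the counts of 1 or 2 calls in these host lists, and those of the neutrophil, basal, hypoxia and oxidative phosphorylation lists, changed when single libraries were left out.

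**Figure D3:**
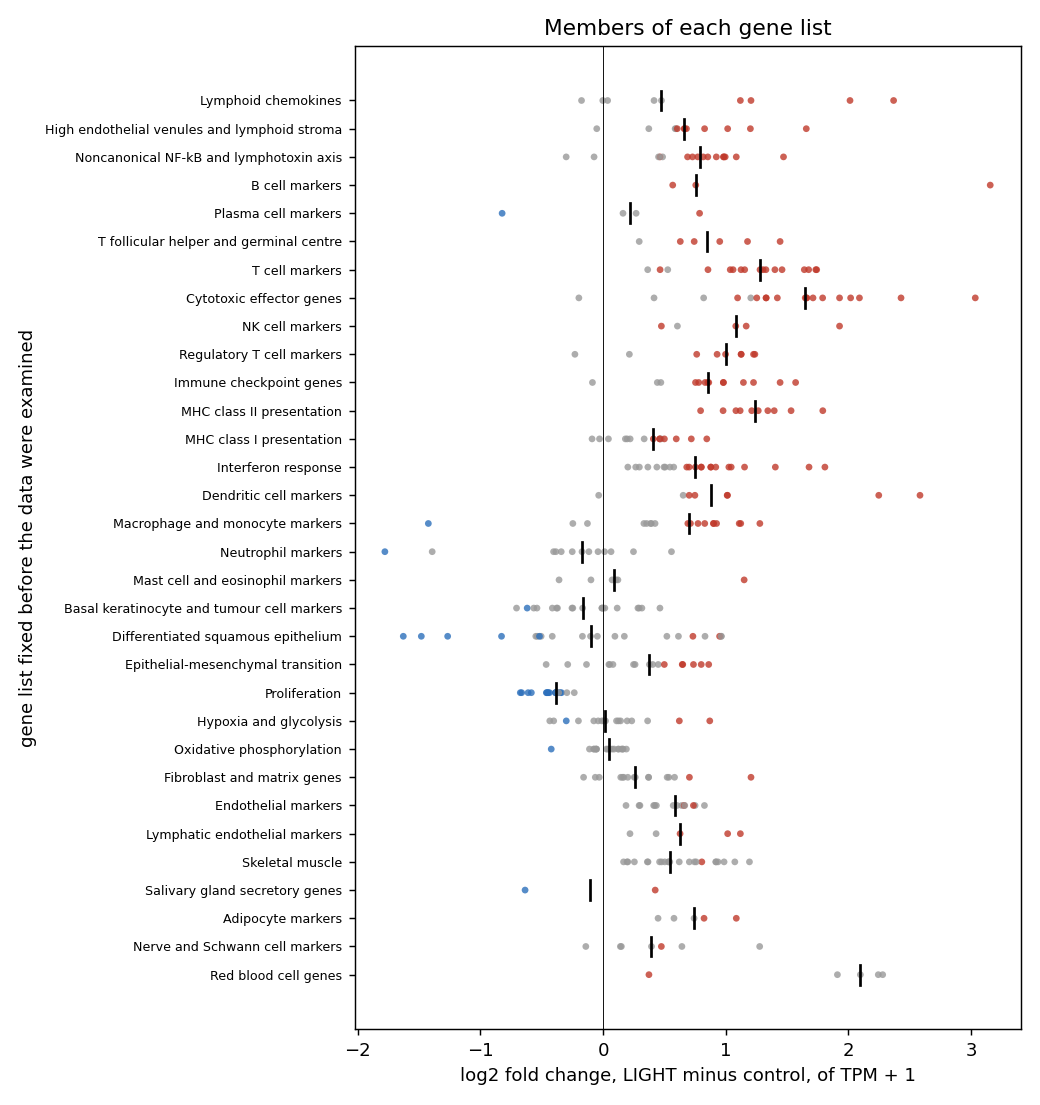
Each point is a tested member of 1 of the 32 gene lists (y axis), placed by its log2 fold change of TPM + 1 (x axis, LIGHT minus control); red and blue are genes with a limma adjusted p under 0.05 and black bars are list medians. The median lies at 1.65 for cytotoxic effector genes, 1.28 for T cell markers and -0.39 for proliferation.

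The first principal component of the 1000 most variable genes held 64.6% of their variance and separated the groups, with control libraries at -26.0, -12.8 and -16.0 and LIGHT libraries at 11.4, 25.7 and 17.7. The second held 19.2%. Spearman correlations were 0.983 to 0.991 within control, 0.978 to 0.987 within LIGHT and 0.941 to 0.976 between the groups.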

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

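The haemoglobin covariate was chosen after seeing the data; all other settings here were chosen before the data were examined. In no setting did a gene called with the deposited values change sign. Of the 3037 called genes, 3030 had all LIGHT libraries on 1 side of all control libraries. Leaving out 1 library or changing the pseudocount could not reverse the sign of these genes. The filters, the replicate block and the other limma fits leave the fold unchanged. For these genes only the scalings and the covariates could have reversed a sign. The counts of 2325 higher and 712 lower genes became 652 and 98 with the skeletal muscle covariate, 946 and 203 with the haemoglobin covariate and 376 and 82 with a minimum log2 fold change of 1, which only removes calls. Quantile normalization gave 1399 higher and 1811 lower genes, and trimmed-mean factors gave 2005 lower genes; both lower the median change of all genes. Leaving out 1 library gave 1264 to 2027 higher and 325 to 791 lower genes, 16 to 20 lists higher and 2 to 4 lists lower. The lists called lower were 4, and 2 with the filter at 5 TPM, 1 with trimmed-mean factors, 1 with quantile normalization and 1 with fry; with an estimated correlation 0 lists were higher and 0 lower. Among 143 named genes besides Tnfsf14, 111 of them called, 43 lost their call with the skeletal muscle covariate, 37 with the haemoglobin covariate, 15 with quantile normalization and 7 to 17 with 1 library left out, each keeping its direction. Apart from the estimated correlation, lists higher numbered 12 to 20 against 18.

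The skeletal muscle list reversed its test direction with its own mean as the covariate, by construction (median log2 fold change 0.036), and the mast cell and eosinophil list reversed with the haemoglobin covariate (-0.56); the cause of the latter was not tested. Tnfsf14 kept its direction and its call in each limma setting, with a log2 fold change between 3.80 and 5.08, and the exact permutation test of 3.99 cannot go below p = 0.1. With a replicate block 2325 genes were higher and 907 lower and 17 lists higher and 4 lower; the red blood cell list was called with it (adjusted p = 0.0169, 5 of 5 genes up against 1), and the endothelial and adipocyte lists were not (adjusted p = 0.0532 each). Same-numbered libraries had correlations of deviations of 0.37, 0.24 and 0.01, and control replicate 3 correlated best with LIGHT replicate 2 (0.33), so the numbers are not shown to pair the samples. Depth is unknown, so its effect on low genes cannot be given.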

Other observations

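The tests of explanations below were chosen after the values were seen, except the counts over other splits; the gene lists in the next paragraph were chosen after the data were seen too, so their counts are not independent evidence.

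Genes of further groups were called, but with an estimated correlation none of these lists was (adjusted p from 0.175 to 0.343). Of 13 tested EGFR ligands and immediate targets 9 fell and 0 rose, including Areg (58.2 to 18.9 TPM), Hbegf (88.8 to 39.6 TPM) and Phlda1 (111 to 51.4 TPM), with a median log2 fold change of -0.57. Complement genes rose in 7 of 11, with C3 going from 62.6 to 212 TPM, and lysosomal genes rose in 13 of 20 while Ctsl fell. Granzymes rose in 7 of 10, guanylate binding proteins in 7 of 9 and Serpina3 genes in 3 of 5, with Serpina3g going from 29.5 to 204 TPM. Of 20 small proline-rich and cornified envelope genes 6 fell, and of 10 kallikreins 3 fell, Klk8 from 688 to 250 TPM. In the NRF2 list 5 of 19 fell and 1 rose, with Gsto1 dropping from 11897 to 5324 TPM. In the IL-17 and IL-36 keratinocyte response list 4 of 14 fell and 2 rose. Microfold cell markers rose in 6 of 11 and fell in 1, plasmacytoid dendritic cell markers rose in 4 of 7, B cell markers without Spib rose in 2 of 2, and cytosolic ribosomal protein genes fell in 1 of 24. Of these 2 B cell markers, Cd22 passed the filter on low values only through the LIGHT libraries.

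T cell, cytotoxic and MHC class II genes were higher in LIGHT tumours by 1.18, 1.51 and 1.25 (mean log2). A lower tumour cell share would raise other cell types alike, but cytotoxic and MHC class II genes rose above the fibroblast list by 1.18 (95% interval 0.33 to 2.04) and 0.92 (0.11 to 1.73). Among stromal and host lists with 5 or more tested members, however, the fibroblast list rose least. Its mean log2 fold change was 0.33, against 0.42 for nerve, 0.54 for endothelial and 0.74 for adipocyte genes, which were not compared. The excess therefore holds over fibroblast genes alone and does not exclude a lower tumour cell share. For T cell genes the first comparison, also with fibroblasts, left this open at 0.86 (-0.11 to 1.82). A second, with the neutrophil list, gave 1.49 (0.41 to 2.58). The second was taken up after the first was undecided, and the neutrophil list itself changed by -0.31 (-0.96 to 0.34). A lower tumour cell share is therefore left open for T cell genes too. With the muscle covariate the changes were 1.54, 1.76 and 1.42, and with the haemoglobin covariate 1.43 for cytotoxic and 1.25 for MHC class II genes, with intervals above 0, but 1.03 (-0.11 to 2.16) for T cell genes, so blood in the specimens may account for part of the T cell change. A response of host cells to LIGHT stays open and was not tested apart from the group itself.

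Spib rose to 14.1 TPM while most B cell genes stayed too low to test. The bound that the highest of Ms4a1, Cd79a, Cd79b and Pax5 stays under 1.21 TPM (the lowest Spib value of a LIGHT library divided by 10) was missed by Cd79b at 1.32 TPM, while Ms4a1, Cd79a and Pax5 averaged 0.04, 0.23 and 0.01 TPM in LIGHT tumours, so B cells as the source are left open with genes this near the floor; a second bound, tried afterwards, is left out here. Siglech, a plasmacytoid dendritic cell gene, reached at most 1.01 TPM in a LIGHT library, too near the floor to exclude those cells, and 4 of 7 tested members of their list rose. A microfold-like epithelial programme is a candidate explanation that stays open, since Gp2 and Sox8 reached at most 0.06 TPM while 6 of 11 microfold list members, several of them also expressed by leukocytes, rose.

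EGFR ligands and immediate targets fell by more than the basal keratinocyte list, with a difference of -0.55 (95% interval -0.88 to -0.21), but the EGFR list was chosen after the data were seen, so the difference may be partly built in and a lower tumour cell share is left open. With Krt4, Krt76, Krt84, Lor and Tgm3 as a measure of host tongue mucosa the change was -0.57 (-1.18 to 0.05) against -0.69 without it, so more mucosa in the LIGHT specimens could not be excluded. A response to LIGHT itself stays open and was not tested.

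Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many called genes as the real one (3037, highest other 0) and 1 as many called lists (22, highest other 20). With 10 splits a share under 0.05 cannot be reached. The other splits mix both groups on each side, so their counts are not those of libraries without a group difference.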
